A study of Mus musculus with 8 samples.

How the data were processed

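Hearts of db/m and db/db mice were profiled by RNA sequencing in 8 libraries, 4 per genotype, and each library was assigned to its group by the genotype in its label. Per the labels' protocols, 3 µg of total RNA per sample went into libraries made with the NEBNext Ultra RNA kit for Illumina, a description that does not say whether strand was kept. The deposited values are whole-number counts per Ensembl gene, not normalised and not pooled over replicates, per the file headers and the values themselves. The reads were processed against mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. The columns are laid out as gene, exon intervals, strand, length and count, and the length in the deposited table, another value per gene, equals the merged exon intervals for all 55573 genes. The 8 files of single samples held the same counts as the table of the whole series. Rows that name no gene numbered 0.

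Gene symbols were taken from GENCODE release M21 on GRCm38, the assembly also called mm10, by Ensembl identifier. Of 55573 identifiers 55480 were found, 55304 of them with the same start and end, and the 93 not found held 2510 counts in all. Coordinates are those of the deposited table on mm10.

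Library sizes, from 19541757 to 22249911 counts, were similar between genotypes. All 37 genes on the mitochondrial chromosome had 0 counts in all 8 libraries. Pseudogenes took 24.7% of all counts, and those near-identical to a mitochondrial gene 12.0%. The 5 genes with the most counts were Myh6 and the pseudogenes Gm28437, Gm10925, Gm29216 and Gm28661, near-identical to mt-Co3, mt-Atp6, mt-Co1 and mt-Co2; together they took 10.5% ± 2.60 of counts in db/m and 13.0% ± 1.31 in db/db (SD, n = 4). Pseudogenes were matched to coding genes with BLAST 2.17.0 at an identity of at least 95% over at least 0.5 of the pseudogene. Of 331 matched pseudogenes with at least 10000 counts, 266 held more counts than the coding gene they resemble. No pseudogene matched to mt-Nd1, mt-Cytb, mt-Atp8 or mt-Nd6 held counts, so such copies do not account for the 0 counts of these genes. How reads that fit several places were assigned was not tested, so genes with such copies are reported as uncertain. Because the use of strand is not stated, overlapping and antisense genes share the same uncertainty.

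Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 17411, and libraries were scaled by TMM factors. The quasi-likelihood F test with robust dispersion had genotype as its single factor, was two-sided and was adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05 on the adjusted p and no minimum fold change. Log2 fold changes are db/db over db/m, with the SE derived from the test. CPM values are relative to the scaled library sizes, and list levels are means over members of log2 CPM with a prior count of 2, compared by two-sided exact permutation of the 8 libraries.

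The 46 gene lists, 32 of pathways and 14 of cell types, were textbook lists fixed before the data were examined, as were the tests, the rule for naming genes and the alternatives not described as added. Lists with at least 5 measured members (43 lists) were tested by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over lists. Of these 17 passed upward and 6 downward, and 0 passed with an estimated correlation or by the rotation test fry, whose p asks whether a list moves one way on balance. In each list the members past 0.05 were also counted with adjustment over the list alone. Lists overlap, most of all the PPAR-alpha list.

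Named genes followed a rule. It takes the 12 genes with the largest change in each direction among those past the threshold with non-overlapping groups and a mean of at least 2 CPM, which gave only Slc38a1. It also takes up to 4 members of each list with the smallest adjusted p or, where none passed, up to 2 members with the highest mean CPM as examples, and allows any member of the 4 lists of fatty acid and branched-chain amino acid degradation. The label-check genes and the 5 most counted genes complete it. Some members named as examples were chosen by their p instead after the values were seen, as were Kcnk1, Hr and the single adipocyte and atrial markers. Some genes that the rule allows are not reported here.

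Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other normalisations, no filter or a stricter filter (1 CPM in 4 libraries), a replicate block, other thresholds, other set tests and leaving out each library. Added after seeing the data were fits without db/m replicates 1 and 3, with pseudogene counts added to their coding gene, without mitochondrial-like pseudogenes, and with the trend of each library on gene length or GC content removed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

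The tests were tried on simulated counts drawn from the means, library sizes and gene-wise dispersions of all 8 libraries. In these, 200 genes with a mean of at least 2 CPM were changed by known folds. For the comparison of db/db with db/m, edgeR called 5.97% of 67 genes changed 1.5-fold, 38.8% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, and 4 of 17191 unchanged genes. DESeq2 called 22.4%, 71.6% and 95.5% of the same steps and 44 unchanged genes, and limma-voom 5.97%, 40.3% and 92.4% and 4 unchanged genes. Unchanged genes were thus called more often by DESeq2 (0.256%) than by edgeR or limma-voom (0.0233% each). Its larger counts of genes in the real data may therefore hold more false calls. Camera called a list raised 1.5-fold and not an unchanged list, with a preset and with an estimated correlation. The simulated genes were drawn independently of each other, while the estimated correlation of the real beta-oxidation list was 0.706. The simulation therefore does not show how often camera falsely calls lists whose genes vary together. With this depth, 4 libraries per genotype and this spread, db/m replicate 3 included, 1.5-fold changes were thus mostly not detectable for single genes.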

Results

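Gene expression was measured by RNA sequencing in hearts of male mice, 24 weeks of age, on the C57BLKS/J background. Each library was made from 3 µg of total RNA. The db/db mouse carries a recessive mutation of the leptin receptor gene and develops obesity and diabetes, and its heterozygous db/m counterpart serves as the non-diabetic control. There were 4 db/m and 4 db/db libraries. Total counts per library ranged from 19541757 to 22249911, with means of 21263800 ± 575454 in db/m and 20884900 ± 1351980 in db/db (SD, n = 4 each). No pair of libraries of the same genotype matched within sampling noise. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

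Lepr, the leptin receptor gene (ENSMUSG00000057722, chromosome 4, 101717404 to 101815352, mm10), had 10.7 ± 7.02 CPM (normalised counts scaled to a common library size) in db/m and 5.76 ± 1.36 in db/db (SD, n = 4). Its log2 fold change of -0.90 (SE 0.40) did not pass edgeR with Benjamini-Hochberg adjustment (adjusted p = 0.383) and was -0.33 (adjusted p = 0.610 by edgeR) without db/m replicate 3, which had 21.01 CPM. The db mutation alters splicing of one receptor form, so the total count of the gene does not by itself identify the genotype. The Y-linked genes Ddx3y (87.1 ± 10.6 against 80.2 ± 4.70 CPM), Uty (21.8 ± 3.24 against 16.9 ± 2.27), Kdm5d (20.4 ± 5.07 against 19.6 ± 2.25) and Eif2s3y (29.1 ± 3.98 against 34.4 ± 2.83) were expressed in all 8 libraries. Xist, the marker of the inactive X chromosome of females, had 0 to 18 counts per library, and the labels give the animals as male.

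The db/db hearts were compared with the db/m hearts to find which genes differ with the diabetic genotype, and the series title directs attention to branched-chain amino acid and fatty acid degradation. The clearest single difference was a loss of Slc38a1, a sodium-coupled transporter of glutamine and other neutral amino acids (ENSMUSG00000023169, chromosome 15, 96571418 to 96642913). Slc38a1 fell by 2.96 on the log2 scale (SE 0.26), a 7.79-fold lower level in db/db, from 39.7 ± 13.6 to 5.08 ± 0.975 CPM (SD, n = 4; edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.00925). All 4 db/db libraries lay below all 4 db/m libraries. The potassium channel gene Kcnk1, at 0.526 ± 0.227 CPM in db/m and 4.43 ± 1.15 in db/db, and the transcriptional co-repressor gene Hr, at 32.0 ± 6.82 and 13.2 ± 0.641 CPM, came next in order of p. Both missed the threshold in edgeR with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.0688 for each), and both were singled out after their values were seen.

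Of 17411 genes tested, edgeR with Benjamini-Hochberg adjustment called 1 lower and 0 higher in db/db, while 2257 had an unadjusted p under 0.05 (892 higher and 1365 lower). DESeq2 called 354 genes (158 higher and 196 lower) and limma-voom with sample quality weights called 130 (72 higher and 58 lower). In simulated counts DESeq2 called 44 unchanged genes and edgeR and limma-voom 4 each, so the DESeq2 count may hold more false calls. In limma-voom the weight of db/m replicate 3 was 0.124, against 0.943 to 2.09 in the other libraries. The groups did not overlap in 1680 genes, or 9.65% of those tested, where chance gives 2.86%. The count turned on single libraries. Without db/m replicate 3 edgeR called 106 genes (64 higher and 42 lower), and the call of Slc38a1 was lost without db/m replicate 1 (adjusted p = 0.0618), db/db replicate 1 (0.0827), db/db replicate 2 (0.126) or db/db replicate 4 (0.103). The direction of Slc38a1 was the same without each of the 8 libraries, which groups that do not overlap make all but certain.

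The control group was not uniform. In db/m replicates 1 and 3, genes of adipocytes and of atrial heart muscle stood far above the other 6 libraries. Ucp1, the uncoupling protein of brown fat, had 1765 and 8220 counts in these libraries and 0 to 2 in the others. Adipoq, the adiponectin gene of fat cells, had 1082 and 2243 counts against 0 to 10, and the atrial genes Sln (4516 and 1589 against 0 to 83) and Bmp10 (2334 and 74283 against 0 to 18) followed the same division. The 83 Sln counts lay in db/m replicate 4, which also had 228 counts of Myl4 and 48 of Mybphl, though only 7 of Bmp10. Fits without db/m replicates 1 and 3 may therefore still hold some atrial counts. Among 30 adipocyte and atrial marker genes with at least 50 counts, both libraries lay above the other 6 in 25. A pair named in advance would do so by chance in 3.57% of genes, but this pair was singled out on these markers. Of 12 further adipose and atrial markers outside the lists, chosen afterwards, both libraries lay above the other 6 in 9 (5 of 8 adipose and 4 of 4 atrial), among them Pck1 with 1417 and 8199 counts against 0 to 10 and Mybphl with 1331 and 1385 against 0 to 48. Values without both libraries therefore stand beside the gene groups that move with them, from 2 db/m against 4 db/db libraries, an alternative chosen after seeing the data. In that fit edgeR called 46 genes (27 higher and 19 lower), of which 36 were also called without db/m replicate 3 alone, all in the same direction. Both fits differ only by db/m replicate 1, so that shared direction is not separate support.

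**Figure D1:**
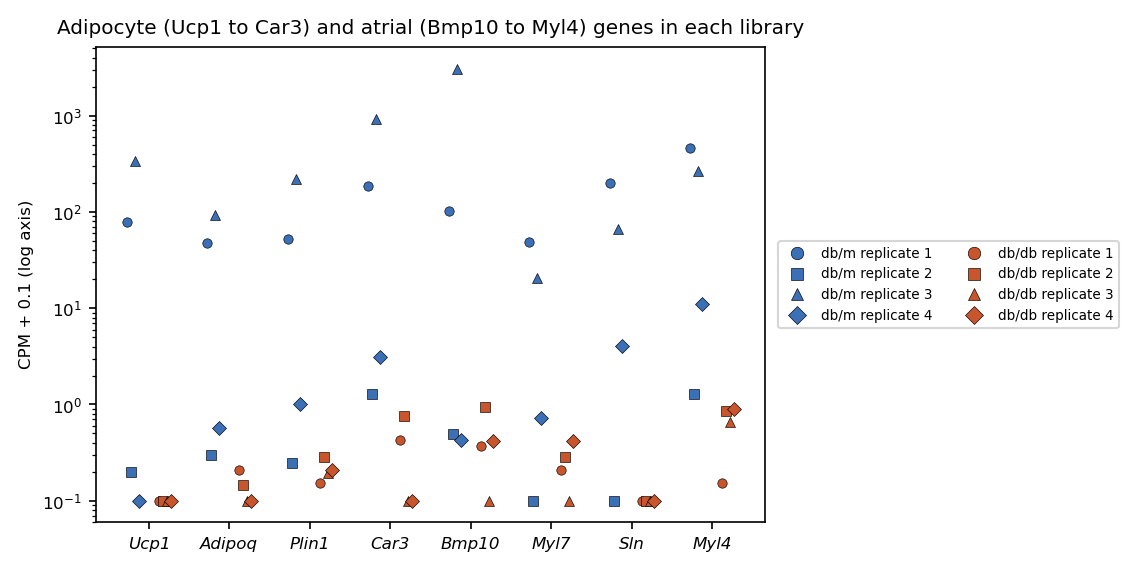
Normalised counts (CPM plus 0.1, log axis) of 4 adipocyte genes (Ucp1, Adipoq, Plin1, Car3) and 4 atrial genes (Bmp10, Myl7, Sln, Myl4) in each of the 8 heart libraries; each point is 1 library. Only db/m replicates 1 and 3, with 1765 and 8220 counts of Ucp1, lie at the top for every gene drawn.

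Genes of mitochondrial fatty acid beta-oxidation rose together in db/db hearts. All 21 measured members had a positive fold change, with a median log2 fold change of 0.74, and 20 of them rose by edgeR when adjusted over the list alone. Slc25a20, the carnitine-acylcarnitine carrier, went from 128 ± 36.2 to 264 ± 42.3 CPM (log2 fold change 1.04, SE 0.22). Acaa2, the thiolase of the last step of each round, went from 477 ± 127 to 908 ± 116 CPM (0.93, SE 0.21), and the dehydrogenases Acadl (0.88, SE 0.23) and Acadm (0.94, SE 0.30) and the trifunctional protein subunit Hadha (0.86, SE 0.22) moved by similar amounts. Cpt1b, the muscle form of the carnitine palmitoyltransferase that admits long-chain acyl groups to mitochondria, was low in these counts, at 2.12 ± 0.624 and 4.44 ± 1.06 CPM (1.07, SE 0.29). Echs1 alone did not pass (0.39, SE 0.28). The mean log2 CPM of the list was 7.31 ± 0.46 in db/m and 8.11 ± 0.16 in db/db (SD, n = 4; two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows; 0.179 after Benjamini-Hochberg adjustment over lists).

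The list passed limma camera with a preset correlation (Benjamini-Hochberg adjusted p = 1.47e-20) and not with an estimated one (adjusted p = 0.405 with an estimated correlation). Without db/m replicates 1 and 3 the median was 0.47, again with all 21 positive and with 17 members higher when adjusted over the list alone. The count over the list alone was 8 without db/m replicate 1 or db/db replicate 4, and 14 to 19 without any other single library. Over all genes tested, edgeR called 0 of the 21 members, of which 20 had an unadjusted p under 0.05, while DESeq2 called 8 and limma-voom 5. Values of Hadhb and Etfa are uncertain, because near-identical pseudogenes hold more counts than these genes.

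Targets of PPAR-alpha, the lipid-sensing nuclear receptor, rose as well, with 13 of 19 measured members higher when adjusted over the list alone, 18 positive and a median log2 fold change of 0.94. The acyl-CoA thioesterases Acot1, from 29.8 ± 13.7 to 111 ± 51.0 CPM (1.89, SE 0.40), and Acot2, from 151 ± 23.9 to 466 ± 218 CPM (1.63, SE 0.32), and Angptl4, an inhibitor of lipoprotein lipase (2.04, SE 0.67), rose. Pdk4, which restrains pyruvate oxidation, had 634 ± 325 and 1865 ± 1424 CPM and did not pass, and db/db replicate 3 had the lowest mean log2 CPM of the list among db/db libraries (6.60 against 7.27 to 7.80). The list passed limma camera with Benjamini-Hochberg adjustment (adjusted p = 1.15e-14; adjusted p = 0.405 with an estimated correlation) and, without db/m replicates 1 and 3, had a median of 0.58. Its count over the list alone was 6 without db/m replicate 1 or db/db replicate 4, 7 without db/db replicate 2 and 9 to 16 otherwise, and Angptl4 (1.35 without db/db replicate 2) lost its call without db/m replicate 1, 3 or 4 or db/db replicate 2 or 4. Of its 19 measured members 14 belong to another list too.

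Peroxisomal fatty acid oxidation moved less. Of 19 measured members 17 were positive, the median log2 fold change was 0.29, and 4 rose when adjusted over the list alone, among them Ech1, a dienoyl-CoA isomerase (1.08, SE 0.30), and Hsd17b4, the bifunctional enzyme of the pathway (0.52, SE 0.13). Abcd2, a transporter of very long-chain acyl groups, had a value of -0.91 (SE 0.35) and did not pass. The list rose by limma camera with Benjamini-Hochberg adjustment (adjusted p = 7.51e-05; adjusted p = 0.497 with an estimated correlation). Without db/m replicates 1 and 3 its median was 0.20, and 0 members passed by edgeR when adjusted over the list alone. The calls of Ech1 and Hsd17b4 were also lost without db/m replicate 1 or db/db replicate 1, 2 or 4. With all 8 libraries, 5 members had an unadjusted p under 0.05, and DESeq2 and limma-voom called 2 and 0 members over all genes.

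**Figure D2:**
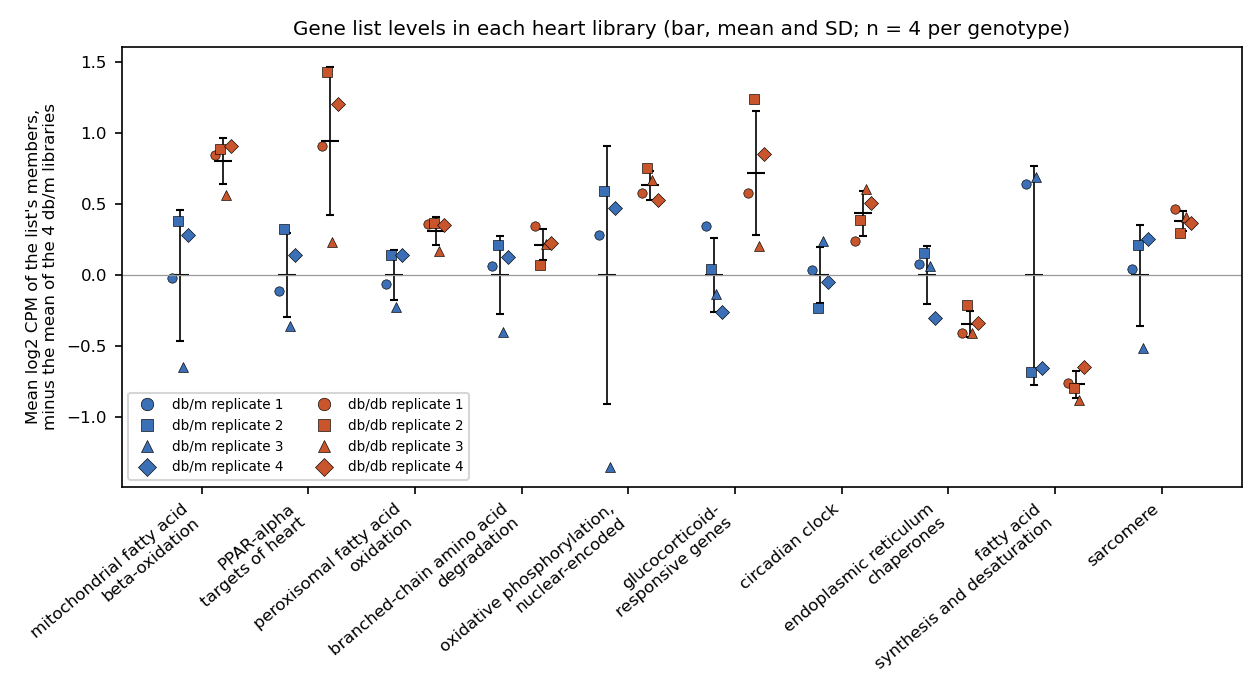
Mean log2 CPM of the members of 10 gene lists in each library, drawn minus the mean of the 4 db/m libraries; points are libraries, bars are mean and SD (n = 4 per genotype). For mitochondrial fatty acid beta-oxidation the 4 db/db libraries lie above all 4 db/m libraries, and db/m replicate 3 is the lowest library for oxidative phosphorylation.

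Genes of branched-chain amino acid degradation did not fall as a group. Of 21 measured members 16 had a positive and 5 a negative fold change, the median log2 fold change was 0.30, and 0 members passed by edgeR, whether over all genes or adjusted over the list alone (2 had an unadjusted p under 0.05; DESeq2 and limma-voom called 0). Among subunits of the branched-chain keto acid dehydrogenase, none of which passed, Bckdha had 21.2 ± 4.31 CPM in db/m and 28.7 ± 4.64 in db/db (log2 fold change 0.44, SE 0.18), Bckdhb had 21.5 ± 3.91 and 17.7 ± 2.60 (-0.28, SE 0.17), and Dbt had 70.4 ± 5.09 and 64.8 ± 9.92 (-0.12, SE 0.14). Bcat2, the mitochondrial aminotransferase of the pathway, had 55.0 ± 19.2 and 73.2 ± 7.06 CPM (0.41, SE 0.25), and Mccc2, a subunit of methylcrotonyl-CoA carboxylase, had 17.1 ± 3.66 and 23.4 ± 3.23 (0.45, SE 0.19).

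The branched-chain list ranked higher than other genes by limma camera with Benjamini-Hochberg adjustment (adjusted p = 0.00718; adjusted p = 0.623 with an estimated correlation). Its median was 0.17 without db/m replicate 3. That call was lost without db/db replicate 1 (adjusted p = 0.0515) and without db/m replicates 1 and 3 (adjusted p = 0.356, median 0.06). Its mean log2 CPM was 5.54 ± 0.27 in db/m and 5.76 ± 0.11 in db/db (SD, n = 4; two-sided exact permutation p = 0.143).

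**Figure D3:**
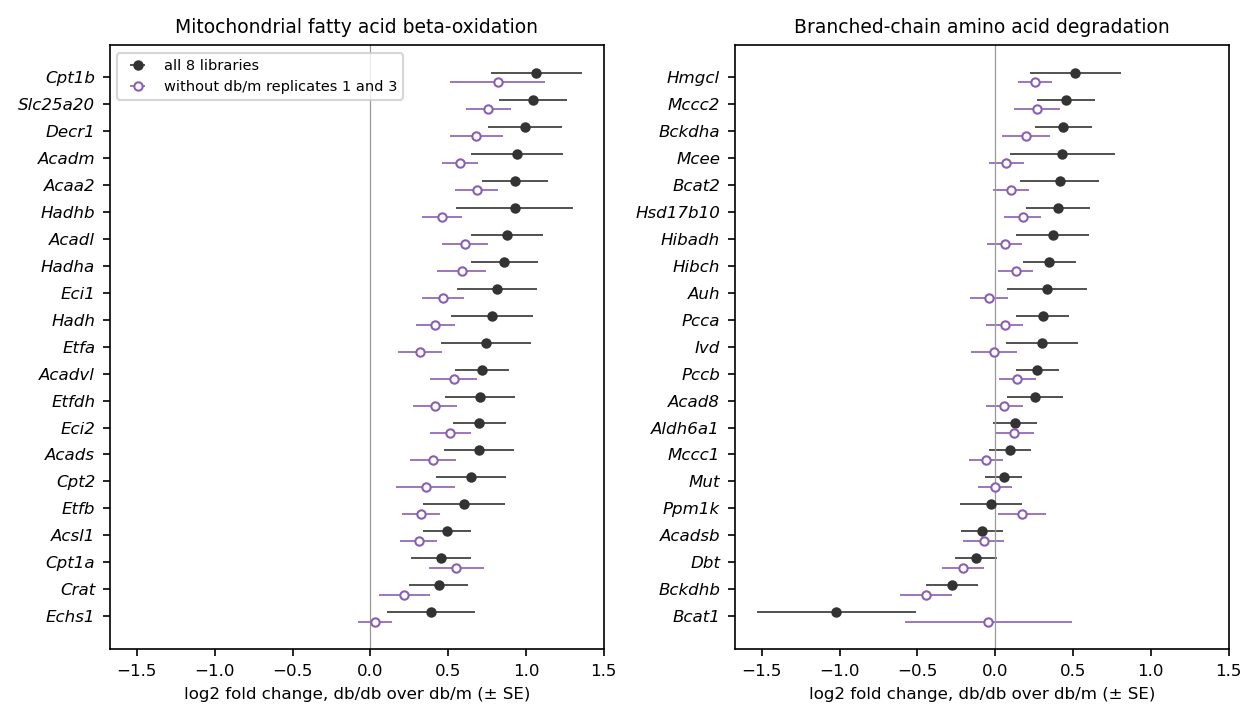
Log2 fold change of db/db over db/m with its SE for each measured member of mitochondrial fatty acid beta-oxidation (left) and branched-chain amino acid degradation (right), with all 8 libraries (filled) and without db/m replicates 1 and 3 (open). All 21 oxidation genes lie above 0 in both fits, while the branched-chain genes spread around 0 in the second, with a median of 0.06.

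Among genes of fatty acid uptake, triglyceride storage and lipolysis, Slc27a1, a fatty acid transport protein, rose from 154 ± 15.7 to 292 ± 57.7 CPM (log2 fold change 0.93, SE 0.17) and was the single member of 26 past edgeR when adjusted over the list alone. Without db/m replicate 3 there were 5 (4 higher and 1 lower), and G0s2, an inhibitor of adipose triglyceride lipase singled out after its values were seen, fell over all genes (-0.76, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0244; -0.51 and 0.455 with all libraries). Without db/db replicate 3 there were 2, both higher. Cd36, the fatty acid translocase, had a log2 fold change of 0.55 (SE 0.20) and rose within the PPAR-alpha list, a call lost without db/m replicate 1 or 4 or db/db replicate 1, 2 or 4. The uptake list had a median of 0.14 (0.23 without db/m replicate 3 and without db/db replicate 3, 0.04 without db/db replicate 2) and passed limma camera with Benjamini-Hochberg adjustment (adjusted p = 0.0159; adjusted p = 0.513 with an estimated correlation). That call was lost without db/m replicate 1 (0.0882), without db/db replicate 4 (0.0922) and without db/m replicates 1 and 3 (0.0900). Fabp3, the heart fatty acid binding protein, is counted mostly in pseudogene copies and its value is uncertain.

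Fatty acid synthesis and desaturation fell in db/db, with 11 of 18 members lower and 1 higher by edgeR when adjusted over the list alone and a median log2 fold change of -0.70 (limma camera with Benjamini-Hochberg adjustment, adjusted p = 2.97e-05; adjusted p = 0.497 with an estimated correlation). The size of this fall lay largely in db/m replicates 1 and 3, the libraries with adipocyte counts. Fasn, the fatty acid synthase, had 484 ± 527 CPM in db/m and 23.4 ± 3.87 in db/db (log2 fold change -4.37), but -0.51 without those libraries, and Scd1, a stearoyl-CoA desaturase, went from -3.46 to -0.33. Without both, the list's median was -0.12 and 3 members were lower; 2 were lower without db/m replicate 3 alone, 6 without db/m replicate 1 or db/db replicate 1, and 7 without db/db replicate 2 or 3. Elovl5, an elongase of polyunsaturated acyl chains, kept its size, with -0.63 (SE 0.12) in all libraries and -0.68 (SE 0.11) without both. Mlxipl, the glucose-sensing transcription factor ChREBP, had -0.71 and -0.73. Cholesterol synthesis had a median of -0.22 and did not pass (limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.0511), with Hmgcs1 at -0.48 (SE 0.15), but passed without db/m replicate 3 (0.0229), db/db replicate 1 (0.0414) or db/db replicate 4 (0.0267; adjusted p = 0.556 to 0.632 with an estimated correlation in these 3 fits).

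Nuclear-encoded oxidative phosphorylation genes rose as a list, and db/m replicate 3 stood below every other library. They were positive in 72 of 73 members with a median log2 fold change of 0.46 (limma camera with Benjamini-Hochberg adjustment, adjusted p = 7.77e-14; adjusted p = 0.513 with an estimated correlation), yet 0 passed by edgeR when adjusted over the list alone, and 1 had an unadjusted p under 0.05 (DESeq2 and limma-voom called 0). Mean log2 CPM of the list was 4.11 in db/m replicate 3 and 5.74 to 6.21 in the other 7 libraries. Without db/m replicate 3 the median was 0.19, and without replicates 1 and 3 it was 0.10. In 23 members near-identical pseudogenes hold more counts than the gene itself. Ndufv1 had a log2 fold change of 0.44 (SE 0.21) and Uqcrc1 of 0.41 (SE 0.20). The list of 13 mitochondrially encoded genes of oxidative phosphorylation had 0 counts in all 8 libraries and was not tested, while pseudogenes near-identical to mitochondrial genes held 12.05% of all counts.

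The tricarboxylic acid cycle was positive in 17 of 18 members (median 0.37; limma camera with Benjamini-Hochberg adjustment, adjusted p = 7.99e-05; adjusted p = 0.513 with an estimated correlation; 0.0849 without db/m replicates 1 and 3), with a median of 0.21 without db/m replicate 3. Its one exception was Pcx, the anaplerotic pyruvate carboxylase, which fell from 58.5 ± 28.2 to 22.8 ± 2.76 CPM (log2 fold change -1.36, SE 0.31) when adjusted over the list alone and had -0.62 (SE 0.13) without both libraries. Pcx lost that call without db/m replicate 1 or any 1 db/db library. Idh2 had 0.82 (SE 0.25). Glucose uptake and glycolysis passed limma camera with Benjamini-Hochberg adjustment with all libraries (adjusted p = 0.0379, median 0.21, adjusted p = 0.645 with an estimated correlation). It lost its call without db/m replicate 3 (0.427), db/db replicate 1 (0.0594), db/db replicate 3 (0.0647) or db/db replicate 4 (0.0548), without db/m replicates 1 and 3 (0.962, median 0.09), with pseudogene counts added (0.0573), with library size alone (0.0575) and with the GC trend removed (0.0839). Pfkl had 0.38 (SE 0.13) and Aldoa 0.46 (SE 0.22). Pyruvate dehydrogenase and its regulators had a median of 0.29 (adjusted p = 0.0396 by limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.513 with an estimated correlation) and lost the call without db/m replicate 1 (0.140), db/m replicate 3 (0.131, median 0.08), db/db replicate 1 (0.0752) or db/db replicate 4 (0.0548). It did not pass without db/m replicates 1 and 3 (0.838), with 7 of 13 members positive and a median of 0.001145. Pdk1 had 0.30 (SE 0.14).

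Within ketone body metabolism, members moved apart. Acat1, the mitochondrial thiolase, rose from 253 ± 80.6 to 413 ± 20.2 CPM (log2 fold change 0.71, SE 0.23), and Slc16a7, a monocarboxylate transporter of ketone bodies and lactate, fell from 22.4 ± 9.81 to 6.19 ± 1.48 CPM (-1.86, SE 0.30), both by edgeR when adjusted over the list alone. Counts over this list, 2 higher and 1 lower, became 3 and 3 without db/m replicate 3, and Acat1 lost its call without db/m replicate 1 or any 1 db/db library. The list itself did not pass (limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.643), and its median of -0.14 differs in sign from its mean of 0.19 and its direction of test. In glycogen metabolism (adjusted p = 0.847 by limma camera, median -0.03), Ppp1r3b, a glycogen-targeting subunit of protein phosphatase, fell from 83.6 ± 20.5 to 39.6 ± 5.41 CPM (-1.08, SE 0.18) when adjusted over the list alone, and the phosphorylase Pygb had 0.51 (SE 0.15). Insulin signalling did not pass (adjusted p = 0.358 by limma camera, median -0.14), with the receptor substrate Irs1 at -0.93 (SE 0.27) and Trib3 at 1.08 (SE 0.32).

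**Figure D4:**
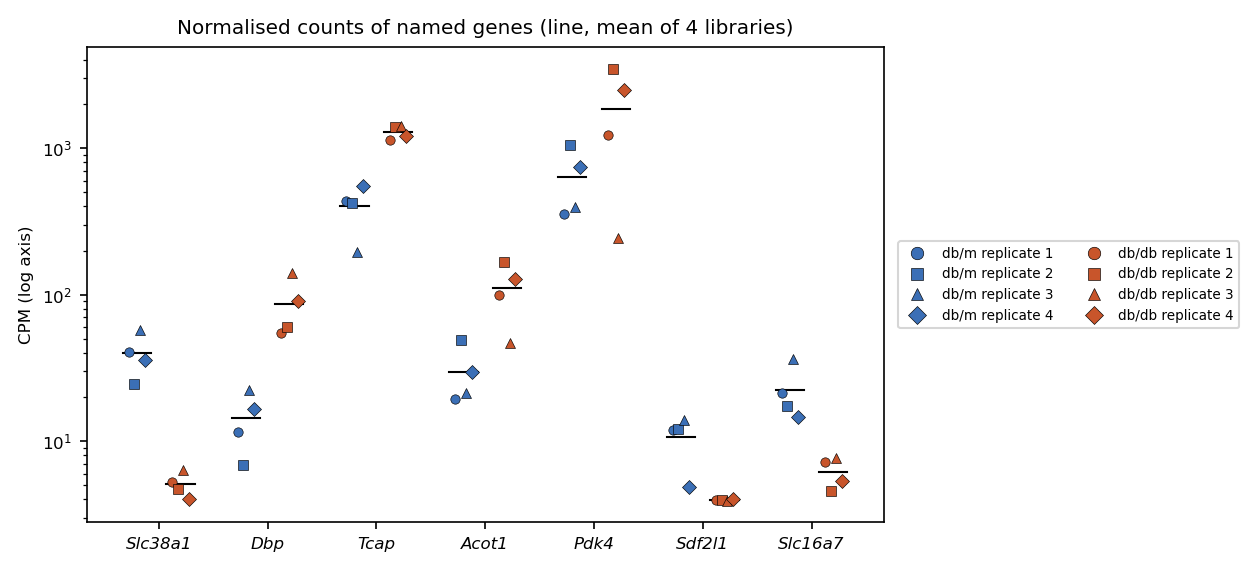
Normalised counts (CPM, log axis) of 7 named genes in each library; points are libraries and the short line is the mean of the 4 libraries of a genotype. Slc38a1 lies at 39.7 ± 13.6 CPM in db/m and 5.08 ± 0.975 in db/db (SD, n = 4), and db/db replicate 3 is the lowest db/db library for Acot1 and Pdk4.

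Sarcomere genes rose as a list, with 21 of 26 positive and a median log2 fold change of 0.30 (limma camera with Benjamini-Hochberg adjustment, adjusted p = 7.99e-05; adjusted p = 0.498 with an estimated correlation; median 0.17 without db/m replicate 3 and 0.11 without db/m replicates 1 and 3). One member, Tcap, the titin cap protein of the Z-disc, rose by edgeR when adjusted over the list alone, from 401 ± 148 to 1298 ± 139 CPM (1.70, SE 0.27), and 4 rose without db/m replicate 3. Mybpc3 had 0.50 (SE 0.14) and Myh6, the main adult myosin heavy chain, -0.12 (SE 0.19). Fetal and stress genes of cardiomyocytes did not pass (adjusted p = 0.646 by limma camera; median -0.04, mean -0.14, direction of test upward). Acta1 had 0.90 (SE 0.30) and Ankrd1 0.68 (SE 0.22), while Nppa, the atrial natriuretic peptide gene, had -2.46 with all libraries and 0.40 (SE 0.97) without db/m replicates 1 and 3. Calcium handling did not pass (adjusted p = 0.643, median 0.11), with Atp2a2 at -0.23 (SE 0.17) and Atp2b1 at -0.40 (SE 0.13). Cardiac ion channels and gap junctions did not pass as a list either (adjusted p = 0.646, median 0.01, mean -0.16, direction of test downward). Within it the pacemaker channel gene Hcn2 fell (-0.78, SE 0.21) and Kcne1, an accessory potassium channel subunit, rose (1.30, SE 0.29), adjusted over the list alone. Kcne1 lost that call without db/m replicate 1 or db/db replicate 1, Hcn2 without db/m replicate 1 or 4 or db/db replicate 1, 2 or 4, and 4 members were higher and 4 lower without db/m replicate 2.

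Extracellular matrix and fibrosis genes were lower in db/db with all libraries, negative in 32 of 34 members with a median log2 fold change of -0.40 (limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.000601; adjusted p = 0.623 with an estimated correlation). This direction followed db/m replicates 1 and 3, the libraries with adipocyte and atrial counts. The call was lost without db/m replicate 1 (0.0689), and without both libraries the list was higher in db/db (0.0389, median 0.11; adjusted p = 0.685 with an estimated correlation). Col3a1 had 189 ± 81.0 and 104 ± 10.8 CPM, with a log2 fold change of -0.86 that became -0.21 without both. The matrix regulator Timp4 rose from 59.1 ± 6.75 to 122 ± 26.2 CPM (1.05, SE 0.17) when adjusted over the list alone. By edgeR 0 of the 34 members were lower over the list alone with all libraries, where 9 lower members had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0 lower over all genes. The same count was 11 without db/m replicate 2 and 0 without any other single library. The list's median was -0.20 without db/m replicate 3.

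Endoplasmic reticulum chaperones fell, with 8 of 19 members lower and 1 higher by edgeR when adjusted over the list alone and a median log2 fold change of -0.41 (limma camera with Benjamini-Hochberg adjustment, adjusted p = 2.97e-05; adjusted p = 0.513 with an estimated correlation; median -0.37 without db/m replicates 1 and 3). Sdf2l1 went from 10.7 ± 3.97 to 3.99 ± 0.0573 CPM (-1.42, SE 0.29), and Pdia4 (-0.72, SE 0.17) and Hyou1 (-0.78, SE 0.20) fell too, while Herpud1, of the degradation arm, rose (0.65, SE 0.17). The 8 lower members became 4 without db/m replicate 1, 3 without db/db replicate 1 or 4 and 2 without db/db replicate 3, where Hyou1 lost its call. Hspa5, the central chaperone BiP, had -0.43 (SE 0.19) and did not pass. The integrated stress response list rose, positive in 20 of 21 members with a median of 0.51 (adjusted p = 7.99e-05 by limma camera; adjusted p = 0.513 with an estimated correlation), though its enzymes varied between db/db libraries, with Psat1 at 12.96 ± 8.87 and Mthfd2 at 20.2 ± 22.1 CPM. Without db/db replicate 2, the highest library for this list, its median was 0.26 (adjusted p = 0.0120 by limma camera; adjusted p = 0.541 with an estimated correlation). None of its members passed by edgeR when adjusted over the list alone (3 without db/db replicate 1 and 4 without db/db replicate 3); 5 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 and 0 over all genes. Antioxidant defence rose (adjusted p = 0.00242 by limma camera, median 0.33; adjusted p = 0.513 with an estimated correlation), led by Nqo1, a quinone reductase, from 28.1 ± 10.4 to 69.0 ± 9.01 CPM (1.30, SE 0.25), catalase (Cat, 0.66, SE 0.16) and Gsta4 (0.84, SE 0.21), each higher when adjusted over the list alone, where Cat lost its call without db/m replicate 1 or db/db replicate 1, 2 or 4, and Gsta4 without these or db/db replicate 3. The antioxidant median was 0.51 without db/m replicate 2, 0.13 without db/m replicate 3 and 0.01 without db/m replicates 1 and 3. Heat shock proteins did not pass (adjusted p = 0.748, median -0.13), although Dnajb4 rose (0.45, SE 0.12) and Hsph1 fell (-1.01, SE 0.31) when adjusted over the list alone, and the list passed downward without db/db replicate 2 (0.0119; adjusted p = 0.541 with an estimated correlation). Both genes lost their calls without db/m replicate 1, 2 (Hsph1 at -0.67) or 4 or db/db replicate 1 or 3, and Hsph1 also without db/db replicate 4.

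Inflammatory cytokines and adhesion molecules did not pass (limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.847; median -0.08, mean 0.02, direction of test upward). Lcn2, the secreted iron-siderophore binding protein lipocalin 2, was its single member to rise, from 2.98 ± 0.833 to 8.42 ± 1.65 CPM (log2 fold change 1.503, SE 0.26), adjusted over the list alone, and the chemokine Cxcl12 had -0.26 (SE 0.23). Interferon-stimulated genes did not pass (adjusted p = 0.847, median -0.03), with Oas2 at -0.87 (SE 0.23). Autophagy and lysosome genes passed upward as a list (adjusted p = 0.00834, median 0.15; adjusted p = 0.513 with an estimated correlation; 0.0744 without db/m replicates 1 and 3), with Sqstm1 at 0.49 (SE 0.15). Of its 21 members 0 passed by edgeR when adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 over all genes. Proliferation did not pass (adjusted p = 0.646, median -0.15). Cytosolic ribosomal proteins rose (adjusted p = 1.58e-05 by limma camera, median 0.32, adjusted p = 0.623 with an estimated correlation, 0.0918 without db/m replicates 1 and 3). In 35 of 40 members, however, near-identical pseudogenes hold more counts than the gene itself. In db/m replicate 3 the list's mean log2 CPM was 2.02 against 3.14 to 3.20 in the other db/m libraries, and without it the median was 0.13, with 31 instead of 38 members positive (0.0431; adjusted p = 0.837 with an estimated correlation). The values of Rpl22 (0.67, SE 0.14) and Rps16 (0.93, SE 0.48) are uncertain because near-identical pseudogenes hold counts. Rpl22, with 12097 counts against 11819 in its pseudogene Gm12005, passed edgeR when adjusted over the list alone but not with pseudogene counts added to their coding gene, nor without db/m replicate 1 or 2 or any 1 db/db library.

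Markers of other cell types were tested in the same way. The atrial cardiomyocyte list was lower in db/db (limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.000429, median log2 fold change -1.52; adjusted p = 0.513 with an estimated correlation), with Myl4 at 185 ± 223 CPM in db/m and 0.539 ± 0.341 in db/db and Dkk3 at 243 ± 308 and 12.99 ± 3.64. Without db/m replicates 1 and 3 it did not pass (0.570, median -0.01), and Dkk3 changed from -4.22 to 0.73 (SE 0.50). White adipocyte markers (adjusted p = 0.0272, median -0.78; adjusted p = 0.513 with an estimated correlation) and brown adipocyte markers (adjusted p = 0.0272, median -0.62; adjusted p = 0.513 with an estimated correlation) were lower too, with Cfd at 37.5 ± 45.8 and 0.159 ± 0.143 CPM and Car3 at 277 ± 436 and 0.245 ± 0.314. Without db/m replicate 3 neither passed (0.551, median -0.12, and 0.334, median -0.19), and without db/db replicate 3 the brown list did not (0.0601). More members pass the low-count filter in some of the fits with 1 library less, and the medians were -4.57 to -8.99 for white adipocyte markers without any 1 library other than db/m replicates 1 and 3, and -3.07 to -3.74 for atrial markers without db/m replicate 2 or any 1 db/db library.

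Fibroblast markers did not pass with all libraries (limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.648, median -0.06, direction of test upward) but were higher in db/db without db/m replicate 1 (0.0341; adjusted p = 0.624 with an estimated correlation) and without replicates 1 and 3 (2.82e-07, median 0.47; adjusted p = 0.559 with an estimated correlation), with Dpep1 at 0.63 (SE 0.20). Markers of mesothelium of the epicardium had a median of -0.70 (adjusted p = 0.823) and of 2.83 without both libraries (0.000229; adjusted p = 0.609 with an estimated correlation). Endothelial (adjusted p = 0.779, median -0.02, with Vwf at -1.56, SE 0.52), lymphocyte (0.823, median 0.02), erythroid (0.758, median -0.13) and Schwann cell and nerve (0.643, median -0.48) markers did not pass. Pericyte and smooth muscle markers missed the threshold (adjusted p = 0.0511, median -0.22, -0.14 without db/m replicate 3), while Acta2, smooth muscle actin, fell from 170 ± 79.4 to 56.1 ± 14.1 CPM (-1.60, SE 0.31) when adjusted over the list alone. That list passed without db/m replicate 1 (0.0240), db/m replicate 2 (0.0468) or db/db replicate 4 (0.0139; adjusted p = 0.474 to 0.604 with an estimated correlation in these 3 fits). Macrophage and monocyte markers were at adjusted p = 0.0511 (median -0.13, Cd68 at -0.53, SE 0.25). Their median was 0.15 without db/db replicate 4 (0.803), the lowest library for this list (2.96 against 3.62 to 4.66 log2 CPM in the other db/db libraries), and -0.07 without db/db replicate 1 (0.285). They passed downward without db/m replicate 3 (0.0229), db/db replicate 2 (0.00280) or db/db replicate 3 (0.000229; adjusted p = 0.469 to 0.837 with an estimated correlation in these 3 fits). The neutrophil list was at adjusted p = 0.0582 (median 1.41, S100a8 at 1.71, SE 0.86, and at 0.22 without db/db replicate 3). Without db/db replicate 3 the list's median was 0.27 (0.602), and it did not pass without db/m replicate 3 (0.276) or db/m replicate 4 (0.306). Neutrophil markers passed upward without db/m replicate 1 (0.0166), db/m replicate 2 (0.0166), db/db replicate 1 (0.00105), db/db replicate 2 (0.0430) or db/db replicate 4 (0.0111; adjusted p = 0.541 to 0.624 with an estimated correlation in these 5 fits). Of the skeletal muscle markers 2 and of the lung epithelium markers 0 passed the filter on low counts, so these lists were not tested.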

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

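Values of 312 groups of 4 libraries were searched for a library whose gap to its nearest neighbour exceeds Dixon's 95% critical value. Each group was a gene, a list or a measure of whole libraries in a genotype. Of these groups 14 held such a library, where chance gives about 1 in 20. The flags are thus no more than chance gives, and a single one is not a finding by itself. Of the tests that follow, the one on gene length and the oxidative phosphorylation level was fixed before its result was seen, and the ones on marker genes were chosen after.

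In db/m replicate 3, 4 values stood apart. Its mean log2 CPM of nuclear-encoded oxidative phosphorylation genes was 4.107 against 5.738 to 6.047 in the other db/m libraries, and that of cytosolic ribosomal proteins was 2.024 against 3.138 to 3.195. Irs1 had 63.12 CPM against 33.72 to 37.90, and Dnajb4 had 112.9 CPM against 120.0 to 120.4. In db/m replicate 1 the cholesterol synthesis level was 4.041 against 3.803 to 3.819, and Ciart had 1.935 CPM against 0.7855 to 0.950. In db/m replicate 2 the erythroid level was 6.547 against 5.384 to 5.545.

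In db/db replicate 3 the peroxisomal fatty acid oxidation level was 5.174 against 5.363 to 5.373, Lepr had 3.731 CPM against 6.243 to 6.677 and Slc27a1 had 205.6 CPM against 314.7 to 328.6. In the same library S100a8, a neutrophil marker, had 27.27 CPM against 2.208 to 4.927. In db/db replicate 1 Acta2 had 35.11 CPM against 60.21 to 64.99, and in db/db replicate 4 the endothelial level was 7.337 against 7.075 to 7.098 and Klf15 had 58.59 CPM against 67.30 to 68.91.

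Across the study, db/m replicates 1 and 3 stand apart from the other 6 libraries. Genotype as the whole cause is argued against by the other db/m libraries, whose log2 excess over db/db (of CPM plus 0.1) had a median of 0.2405 over 30 adipocyte and atrial marker genes (quartiles -0.2537 and 1.142), against 5.178 (1.267 and 8.473) in db/m replicates 1 and 3. The pair was singled out on these same genes, which can widen the gap. A smaller part of genotype stays open, since db/m replicates 2 and 4 both lay above all 4 db/db libraries in 6 of the 30, where chance gives 6.67% of genes. Pieces of fat and atrium in these libraries, from dissection, are a candidate explanation, and both libraries lay above all 6 others in 9 of 12 further markers of these tissues outside the lists on which the pair was singled out (25 of the 30 in those lists). The abundant transcripts of these tissues were present, with Ucp1 at 1765 and 8220 counts and Bmp10 at 2334 and 74283. Of the 30 markers 13 did not pass the filter on low counts and are left out of the fits that use it, while DESeq2, run without it, called 5 of 12 measured white adipocyte members lower over all genes.

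In db/m replicate 3 the deviation of a gene's log2 CPM from its mean over the 8 libraries also correlated with gene length (Spearman 0.439 across genes, which are not independent replicates, against -0.331 to -0.0361 in the other 7). With each library's trend on gene length removed, its oxidative phosphorylation level still lay 1.388 log2 units below the lowest other library (1.63 before removal), where the range of the 7 others was 0.397.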

How the results depend on the processing

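The added fits named in the methods were chosen after seeing the data. RLE factors, the stricter filter and removal of mitochondrial-like pseudogenes left every list and named gene they cover on its side of the threshold. By DESeq2 edgeR's 1 gene became 354 (158 higher, 196 lower), by limma-voom 130 (72 and 58), with no filter 27 (18 and 9), with the length trend removed 14 (8 and 6), with the GC trend removed 2 (0 and 2) and without db/m replicates 1 and 3 46 (27 and 19). Leaving out 1 library in turn gave 0 to 106 genes, 0 to 64 higher and 0 to 42 lower. Fewer libraries with adipocyte counts enter some of these fits, and limma-voom gave db/m replicate 3 a weight of 0.124, against 0.943 to 2.09 in the others. Otherwise the cause was not tested. Of 103 named genes, 51 passed by DESeq2, 26 by limma-voom and 9 with no filter in addition to Slc38a1, and none lost its call there. Library size alone shifted the median log2 fold change of all genes to -0.134 from -0.0187.

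Adjusted p of the lists ranged, over libraries left out in turn, from 1.03e-27 to 2.34e-16 for beta-oxidation, 2.22e-25 to 8.33e-10 for PPAR-alpha targets, 9.39e-06 to 0.000755 for peroxisomal oxidation and 0.000503 to 0.0515 for branched-chain degradation. In the same order they were 0.405, 0.405, 0.497 and 0.623 with an estimated correlation and 0.175, 0.175, 0.175 and 0.367 by fry, and branched-chain degradation was at 0.356 without db/m replicates 1 and 3. Of 183 calls of lists by camera with 1 library left out, 0 held with an estimated correlation (lowest adjusted p 0.197).

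Direction of a list here is that of the camera test, which compares it with other genes. Lists that changed direction in at least 1 fit that left out a single library ranged in adjusted p from 0.0695 to 0.675 for ketone body metabolism, 0.499 to 0.987 for glycogen, 0.129 to 0.844 for insulin signalling, 0.301 to 0.977 for ion channels, 0.328 to 0.994 for inflammatory cytokines, 0.105 to 0.963 for interferon-stimulated genes, 0.0119 to 0.910 for heat shock proteins, 0.391 to 0.994 for proliferation, 0.0341 to 0.921 for fibroblast, 0.289 to 0.964 for endothelial, 0.576 to 0.994 for lymphocyte, 0.0823 to 0.910 for erythroid and 0.0886 to 0.870 for mesothelium markers. Without db/m replicates 1 and 3 the direction reversed for glycolysis (adjusted p = 0.962), ketone bodies (0.0821), insulin signalling (0.849), calcium handling (0.838), extracellular matrix (0.0389), proliferation (0.838), lymphocyte (0.346), mesothelium (0.000229) and Schwann cell markers (0.141), and for the genes Nppa (0.3956 log2) and Dkk3 (0.7341 log2); the medians of glycolysis, ketone bodies and calcium handling kept their sign. With the length trend removed it reversed for glycogen (0.992), insulin signalling (0.963) and lymphocyte (0.992), with library size alone for mesothelium (0.865), and for inflammatory cytokines by ranks (0.888) and without shared members (0.763). Calls lost elsewhere were white adipocyte markers with library size alone (0.0575) and by ranks (0.0786), fatty acid uptake by ranks (0.0798) and without shared members (0.167), and pyruvate dehydrogenase without shared members (0.0737). Cholesterol synthesis passed with library size alone (0.0430) and by ranks (0.0485), neutrophil markers in the same fits (0.0203 and 0.0410), pericyte markers with the GC trend removed (0.0411), macrophage markers with the GC trend (0.0411) or length trend (0.0145) removed and by ranks (0.0445), and calcium handling with the length trend removed (0.0411). The cause was not tested.

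Replicate numbers are shared by the genotypes, but deviations of same-numbered libraries correlated at -0.0882, 0.0561, 0.0268 and 0.0163. None exceeded the 0.1 required for pairing, and 1 of 4 libraries correlated best with its own number. No pairing by number was thus detected, but a pairing hidden by other differences between libraries is not excluded. With the replicate block edgeR called 5 genes (3 higher, 2 lower), and inflammatory cytokines (0.848) and mesothelium (0.796) reversed, while pericyte and smooth muscle (0.0334) and macrophage and monocyte markers (0.0101) and the gene Dbp passed. With 19541757 to 22249911 counts per library and 4 libraries per genotype, 1.5-fold changes of single genes were mostly not detected in simulated counts. Depth was not tested apart from the number of libraries or from the spread between them.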

Other observations

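Of the tests given here, the counts of other splits were fixed before their results were seen, except the one without db/m replicate 3, and that one, the tests on clock genes and the tests on the rise of fatty acid oxidation were chosen after.

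Circadian clock genes differed between the genotypes in opposite directions. Of 20 measured members, 10 rose and 4 fell by edgeR when adjusted over the list alone, and the list passed upward by limma camera with Benjamini-Hochberg adjustment (adjusted p = 0.000179, median log2 fold change 0.61; adjusted p = 0.405 with an estimated correlation). Dbp, an output factor of the clock, went from 14.3 ± 6.69 CPM in db/m to 86.2 ± 39.2 in db/db (SD, n = 4; log2 fold change 2.59, SE 0.40), and the repressors Per2 (1.73, SE 0.31) and Ciart (2.12, SE 0.49) rose with it. The counts were 6 and 4 without db/m replicate 2 and 6 and 2 without db/db replicate 3. Arntl, which encodes the activator BMAL1, fell (-1.49, SE 0.44), as did its partner Npas2 (-1.06, SE 0.33).

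Glucocorticoid-responsive genes rose, with 7 of 19 members higher when adjusted over the list alone, 18 positive and a median of 0.64, or 0.97 without db/m replicate 1 (limma camera with Benjamini-Hochberg adjustment, adjusted p = 9.59e-11; adjusted p = 0.405 with an estimated correlation). Fkbp5, the co-chaperone of the glucocorticoid receptor, went from 29.1 ± 6.49 to 63.7 ± 21.1 CPM (1.13, SE 0.24), Zbtb16 from 42.4 ± 6.28 to 84.9 ± 20.2 and Sult1a1 from 16.5 ± 3.45 to 38.7 ± 5.74 (1.23, SE 0.18). Klf15 (0.52) and Trim63, a muscle ubiquitin ligase (0.64), rose too. Immediate-early genes had a median of 0.31 (adjusted p = 0.00242 by limma camera; adjusted p = 0.513 with an estimated correlation), with Btg2 (1.04, SE 0.25) and Zfp36 (0.65, SE 0.18) higher when adjusted over the list alone. Btg2 lost that call without db/m replicate 2, 3 or 4 or db/db replicate 1, and Zfp36 without db/m replicate 2 or 4 or db/db replicate 1, 2 or 3. That list did not pass without db/m replicate 2 (0.0702) or db/m replicate 4 (0.0536). Without db/m replicates 1 and 3 its median was 0.67, with 18 of 19 members positive (adjusted p = 1.16e-08 by limma camera with Benjamini-Hochberg adjustment; adjusted p = 0.193 with an estimated correlation).

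For the clock genes, fat and atrial tissue in db/m replicates 1 and 3 is argued against as the cause, since without both libraries 18 members passed over the list alone. Of these 5 were lower in db/db. Members that move in opposite directions are what a difference in the clock time at which hearts of the genotypes were collected could give. The labels give no collection times, so collection time and genotype cannot be told apart. A change of the cardiac clock or of feeding rhythm with the genotype stays open and untested.

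The rise of mitochondrial fatty acid beta-oxidation is the pattern that the title of the series asks about. Tissue in db/m replicates 1 and 3 is argued against as the whole cause by the median log2 fold change without both, 0.4655, although it is smaller than the 0.7416 of all libraries. A trend with gene length (0.7598 with the trend removed) and reads placed on pseudogenes (0.7118 with these counts added to the coding gene) are argued against as well. A rise with the diabetic genotype remains as a hypothesis, found and tested on the same data. Collection time, which the labels do not give, cannot be told apart from genotype for this list either. RNA quality, which may also differ between libraries, has no value here beyond the length trend.

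Every split of the 8 libraries into groups of 4, 35 in all, was fitted in the same way. For edgeR 2 of the 35 splits gave as many genes, the real one included, with 1 gene in the real split and at most 1 in the others, so chance is not excluded for that count. By DESeq2 the real split was the only 1 of 35 with as many, at 354 genes against at most 67. The next highest DESeq2 counts, 67, 66 and 62, came from splits with db/m replicates 1 and 3 in the same group. By limma-voom the real split was also 1 of 35, at 130 against at most 5. In the real split limma-voom gave db/m replicate 3 a weight of 0.124, the lowest of all libraries, so its count rests little on that library. First rank is the best that 35 splits allow, and chance gives it 1 time in 35. Chance is thus unlikely for each count taken by itself but not excluded, with no allowance for the number of tools tried. By edgeR without db/m replicate 3 the real split was 1 of the 35 splits of the 7 libraries, at 106 against at most 4, but this fit was singled out of the 8 that leave out a library by its count, so its rank does not decide. Beta-oxidation was 1 of 35 as well, with an unadjusted camera p of 3.42e-22 against 4.53e-19 in the next split, again a rank that chance gives 1 time in 35. It was the 1 list of the 43 split in this way whose real split ranked first, where chance gives about 1.23, so chance is not excluded over all lists. For the 3 other lists of fatty acid and branched-chain degradation chance is not excluded either. Splits as strong numbered 3 of 35 for PPAR-alpha targets (5.35e-16 against 5.36e-21), 3 for peroxisomal oxidation (1.40e-05 against 2.86e-06) and 12 for branched-chain degradation (0.00284 against 1.70e-07). As many lists as the 23 of the real split were called in 8 of 35 splits, with up to 26 in the others. All 8 had db/m replicates 1 and 3 in the same group. Splits with both in the same group gave 18 to 26 lists, and splits with them apart 7 to 22. This points to a structure of the samples, at least in part that of these libraries, which camera with a preset correlation reads as change.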
